A study of Arabidopsis thaliana with 18 samples.

How the data were processed

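RNA was sequenced from Arabidopsis thaliana seedlings of the Col-0 accession, aged 9 days and grown on vertical plates. Plants were wild type (WT) or carried the mutation combination that the labels call bon123t, written here as bon123, a triple mutant of the BONZAI genes BON1, BON2 and BON3, which encode copines (calcium-dependent phospholipid-binding proteins). What the letter t stands for is not given in the sources used here. Each genotype was given a mock treatment, 100 µM abscisic acid (ABA, the hormone of drought and osmotic stress) or 300 mM mannitol (an osmoticum) on 1/2 MS medium, with 3 libraries for each of the 6 groups and 18 libraries in all. The labels of the samples state 12 h of treatment and the text of the series states 24 h, so the duration is uncertain. Total RNA was taken with Trizol, libraries followed standard Illumina procedures, and sequencing was on a HiSeq 2500. Whether libraries were stranded is not given in the sources used here.

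The submitters' processing notes name HISAT2 2.1.0, RSEM 1.3.1, DESeq2 1.24.0 and the genome build TAIR10, without roles or order. The deposited table holds values in TPM (a measure in which all transcripts of a library share a fixed total) that the authors made, 1 column per library, with no further scaling between libraries. The header names no unit. The unit was read from the values, which have 2 decimals and sum to 999989 to 999999 in each library. TPM keeps no record of read depth, so the depth of each library is unknown, no count-based interval can be given, and the precision rests on the spread between the 3 libraries of a group. The table lists 33082 genes, 5905 of them at 0 in every library, and 250 assembled loci have no TAIR identifier. A further line of the table was not analysed here. Names, synonyms and neighbour relations came from the RefSeq annotation of TAIR10.1, matched by locus for 32547 identifiers, of which 14018 carry a symbol. No coordinates were used. Overlapping genes and near-identical copies (KIN1 and KIN2, the LHCB1, LHCB2 and RBCS genes) share reads, and their single values are uncertain.

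The tests planned before the data were examined assumed counts. As that plan foresaw for normalized values, limma-trend was used instead. Values were taken as log2(TPM + 1), genes with at least 1 TPM in at least 3 libraries were kept (21727 genes), and limma 3.58.1 in R 4.3.3 was fitted to all 18 libraries with a mean for each of the 6 groups, trend on and two-sided moderated tests. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called, and said to rise or fall, at an adjusted p under 0.05. The pseudocount of 1 makes fold changes of weakly expressed genes smaller than their ratios. Log2 fold changes are given with their standard error (n = 3 libraries per group). The replicates are not said to come from separate cultures, so the p-values measure the spread between these samples. There were 9 comparisons: ABA against mock and mannitol against mock in each genotype, bon123 against WT in each of the 3 treatments, and the interactions of genotype with ABA and with mannitol. An interaction is the response of bon123 minus that of WT. The fit was tested on simulated data for the 21727 genes, with WT ABA values changed for 50 genes at each fold. Of these 50, 17 were called in the right direction at 1.5-fold, 34 at 2-fold, 50 at 4-fold and 49 at 8-fold, with 7 false calls, and 0 genes were called in the unchanged interaction with mannitol.

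Gene lists were fixed before the data were examined. They are the BON family; ABA and dehydration marker proteins; clade A PP2C phosphatases; ABA receptors; SnRK2 kinases; ABA-related transcription factors; ABA synthesis and breakdown. Others are compatible solute metabolism, DREB/CBF and early dehydration genes, salicylic acid and systemic immunity, NLR immune receptors, pattern-triggered immunity, jasmonate, ethylene, photosystems and Rubisco, chlorophyll synthesis, and senescence and chlorophyll breakdown. The rest are cell wall loosening and cellulose, mitotic cell cycle, auxin, type-A cytokinin response regulators, aquaporins, calcium pumps, channels and sensors, flavonoid and anthocyanin, wax and suberin, heat shock, circadian clock, root hair and endodermis markers, and stomatal lineage and guard cell markers. Of 463 members written, 461 were kept and 2, whose symbols did not match their loci, were dropped. The 28 lists other than the BON family were tested in each comparison with camera from limma, with the correlation between genes estimated, and adjusted by Benjamini-Hochberg over the 28 lists. Members called over all tested genes and called when adjusted over the list alone were counted. The genes named follow a rule written beforehand. It takes the BON genes, the 8 largest rises and 8 largest falls among called genes with a symbol, a mean log2 value of at least 2 and no overlap between the libraries of both groups (10% of unchanged genes would be so separated), up to 4 called members of each list with at least 3 called members, and PR1, ICS1, PAD4, SNC1, RD29A, RD29B, NCED3 and P5CS1 whatever their result. A selection of these is printed. In the interactions the separation of libraries was not asked for.

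A response score per library was the mean log2(TPM + 1) of genes that rose minus that of genes that fell at least 2-fold in the average effect over both genotypes. Treated minus mock scores were compared between genotypes by an exact permutation of the genotype labels within treatments (two-sided, 400 arrangements, smallest possible p 0.005). Because these arrangements also mix the overall difference between genotypes into the score, their p-values answer the question of a response difference imperfectly. Overlaps of 2 responses were compared with the number expected for independent responses. As the responses share the 3 mock libraries, correlations and covariances across genes are given beside those of 100 simulated sets of unchanged groups with the same sharing. Gene ontology terms given in the deposited table (biological process, 15 to 300 genes, 539 terms) were tested among genes called with at least 2-fold changes by one-sided Fisher's exact tests against the 16536 annotated tested genes, adjusted over 7546 tests. Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for tables, these tests and figures.

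The alternatives planned beforehand and run were no filter on low values, the replicate number as a block, only the groups compared, a 2-fold minimum, an adjusted p under 0.01, each library left out in turn, camera with a preset correlation of 0.01, fry, and score genes at any fold. The count-based alternatives (DESeq2, edgeR factors, filterByExpr, scores on scaled CPM) do not apply to TPM and were not run, and the planned stricter filter coincides with the filter used. Chosen after seeing the data were pseudocounts of 0.1 and 5, a minimum of 5 TPM, scaling by the median of ratios to a mean library or to equal upper quartiles, leaving out the 4 ribosomal RNA genes, and removal of each library's lowess trend (span 0.5) with transcript length. That last step also centres each library. Scaling was examined because the median fold change of all genes was far from 0 in several comparisons. The enrichment of terms was repeated on values with the length trend removed.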

Results

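Transcript levels were measured by RNA sequencing of whole 9-day seedlings in 6 groups of 3 libraries: WT and bon123, each after mock treatment, 100 µM ABA or 300 mM mannitol. The values are TPM, so each library sums to nearly the same total (999989 to 999999) and its read depth is unknown. Between 21893 and 24036 genes were listed above 0 in a library. Pearson correlations of log2(TPM + 1) across genes were 0.974 to 0.982 between the WT mock libraries, 0.983 to 0.985 in WT ABA, 0.978 to 0.984 in WT mannitol, 0.984 to 0.987 in bon123 mock, 0.958 to 0.989 in bon123 ABA and 0.984 to 0.987 in bon123 mannitol. The lowest of these involves bon123 ABA replicate 3. That library also had a median-of-ratios factor of 0.637, against 0.861 and 0.811 in replicates 1 and 2. Its BON2 level was 2.85 TPM, against 8.54 and 7.17 TPM in these. Ribosomal RNA made up 10.1%, 5.90% and 7.01% of the total in the 3 bon123 mannitol libraries and 6.10% in WT mock replicate 1, against 0.475% to 2.21% in the other 14.

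**Figure D1:**
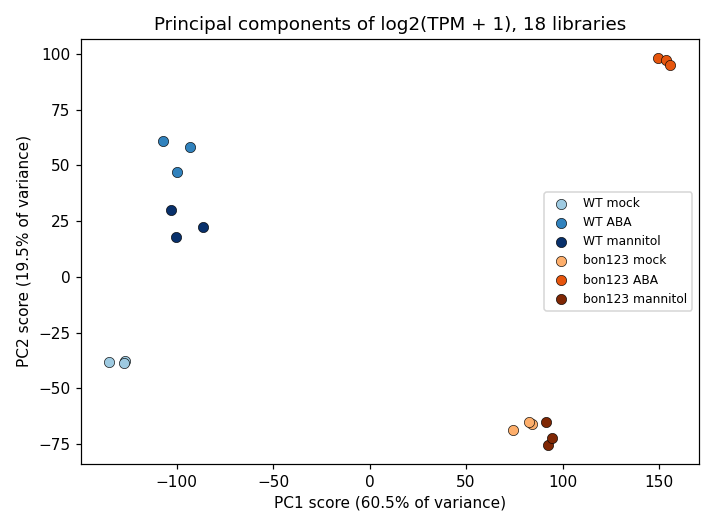
Scores of the 18 libraries (points, coloured by group) on the first principal components of log2(TPM + 1), PC1 on the horizontal axis and PC2 on the vertical axis, without units. PC1 holds 60.5% of the variance and separates the genotypes, and PC2 holds 19.5% and places the ABA libraries of both genotypes and the WT mannitol libraries above mock, with bon123 mannitol near bon123 mock on these 2 axes (PC3, not drawn, holds 7.1% and separates them).

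The first question was whether the mutant libraries lack transcripts of the mutated copine genes. BON1 and BON2 were lower in bon123 than in WT in all 3 treatments. BON3 was barely detected in either genotype, and was not lower in bon123. BON1 (AT5G61900) was at 10.1 to 18.3 TPM in the 9 WT libraries and at 0.25 to 1.66 TPM in the 9 bon123 libraries. Its log2 fold change in bon123 against WT was -2.40 ± 0.18 (SE, n = 3 per group, here and throughout) in mock, -3.03 in ABA and -3.57 in mannitol. BON2 (AT5G07300) was at 21.3 to 36.3 TPM in WT. In bon123 it was at 14.9 TPM on average in mock, 6.19 in ABA and 4.07 in mannitol, with log2 fold changes against WT of -1.1 ± 0.23, -1.82 and -2.58. BON3 (AT1G08860) was at 0 to 0.17 TPM in WT and 0.22 to 0.75 TPM in bon123, below the filter on low values. Each bon123 library was thus above each WT library, so a loss of BON3 transcripts, which the genotype label would allow, was not seen.

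In WT, the comparison of ABA with mock asked which genes the hormone changed. ABA raised the classical dehydration genes, among them late embryogenesis abundant (LEA) proteins that protect dehydrating cells, and the PP2C phosphatases that switch ABA signalling off again. Most transcription factors of ABA signalling, heat shock chaperones, genes of chlorophyll breakdown and genes of cuticular wax and suberin rose with them. Most ABA receptors, cell wall loosening enzymes, cell cycle genes, auxin genes and cytokinin response regulators fell. Most genes of the immunity lists were not called.

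After ABA in WT, 10759 of 21727 genes were called, 4116 higher and 6643 lower, of which 1521 and 1676 changed at least 2-fold. The median log2 fold change of all genes was -0.11. With the median-of-ratios scaling 4818 were higher and 6126 lower, and with the length trend removed 5720 were higher and 6202 lower. The largest rises were of LEA7 (AT1G52690) at 8.25 ± 0.60, the lipid transfer protein gene LTP4 (AT5G59310) at 7.83 ± 0.45, RD29B (AT5G52300), a dehydration protein gene, at 7.32 ± 0.62 and the chaperone gene HSP22.0 (AT4G10250) at 7.09 ± 0.23. EARLI1 (AT4G12480), which encodes a cell wall protein, fell most (-5.31 ± 0.41), followed by DR4 (AT1G73330), a protease inhibitor gene, at -4.87 and the expansin gene EXPA8 (AT2G40610) at -4.75 ± 0.17. Genes named for the largest changes are those whose groups did not overlap, as 10% of unchanged genes would by chance.

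Of 21 ABA and dehydration marker genes, 20 rose in WT after ABA (median 3.88, adjusted p = 0.0447 with an estimated correlation). Of 17 ABA-related transcription factor genes, 16 rose (2.32, adjusted p = 0.0447), with the NAC gene NAC019 at 4.46 ± 0.15 and the ABI5-binding protein gene AFP1 at 4.01. Of 12 heat shock genes, 10 rose and 1 fell (3.46, adjusted p = 0.0447). These 3 lists passed as did the markers in bon123 after ABA, and none of the 4 passed when bon123 mock or bon123 ABA replicate 1, 2 or 3, WT mannitol replicate 1 or 3, or bon123 mannitol replicate 3 was left out (0 lists passed in any comparison). Without WT mannitol replicate 2 or bon123 mannitol replicate 1 or 2, 2 lists passed, and without WT mock replicate 2 the heat shock list did not (median 3.52). With the replicate number as a block none of the 4 passed (adjusted p = 0.0756 for the 3 WT lists and 0.0954 for the bon123 markers). All 9 PP2C genes rose (3.02, adjusted p = 0.0862), HAI1 (AT5G59220) by 5.30 ± 0.31 and HAI3 by 5.80 ± 0.20, and 15 of 16 senescence and chlorophyll breakdown genes rose (2.15, adjusted p = 0.0584, passing without WT ABA replicate 2 at a median of 2.28), with the sugar transporter gene SAG29 at 5.11 ± 0.12. The list of wax and suberin genes had 12 rises and 1 fall of 16 (1.36, adjusted p = 0.271), with CER1, an enzyme of wax alkane synthesis, at 3.49. ABA synthesis and breakdown had 7 rises and 1 fall of 11 (1.59, adjusted p = 0.12), with the ABA hydroxylase gene CYP707A1 at 3.44 and the synthesis gene NCED3 (AT3G14440) at 2.85 ± 0.22. Compatible solute metabolism had 8 rises and 2 falls of 12 (1.62, adjusted p = 0.337), with P5CS1 (AT2G39800), the proline synthesis gene, at 2.95 ± 0.20. DREB/CBF and early dehydration genes had 7 rises and 1 fall of 9 (0.56, adjusted p = 0.313), and SnRK2 kinases 6 rises and 1 fall of 10 (0.59, adjusted p = 0.337).

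Receptor genes of ABA fell in 6 of 10 cases in WT after ABA (median -1.05, adjusted p = 0.152), with PYL4 at -3.12 ± 0.15. Type-A cytokinin response regulators had 8 falls and 1 rise of 9 (-1.77, adjusted p = 0.17), ARR7 at -3.13 and ARR16 at 2.62. Falls numbered 16 of 18 for the mitotic cell cycle (-0.76), 10 of 12 for chlorophyll synthesis (-0.55) and 12, with 4 rises, of 22 for cell wall loosening and cellulose (-0.90), each with adjusted p = 0.337. Auxin genes had 10 falls and 2 rises of 18 (-0.60, adjusted p = 0.493), and root hair and endodermis markers 7 falls and 1 rise of 13 (-0.81, adjusted p = 0.766). Photosystem and Rubisco genes had 8 falls of 37 (-0.26, adjusted p = 0.867), which became 2 with the median-of-ratios scaling and 3 when adjusted over the list alone. Salicylic acid and systemic immunity had 1 rise and 4 falls of 23, with a median of -0.04 that turned to 0.01 with the median-of-ratios scaling and 0.06 with the length trend removed. NLR immune receptors had 1 rise and 5 falls of 18 (-0.23), pattern-triggered immunity 1 and 6 of 19 (-0.20) and stomatal lineage and guard cell markers 0 and 3 of 8 (-0.17). Jasmonate had 3 and 6 of 20, evened to 4 and 4 by the median-of-ratios scaling. The ethylene list had 7 and 4 of 17, with a median of -0.04 that turned to 0.02 and 0.09 with the ratio scaling and the length trend removed, aquaporins 5 and 3 of 19 (0.07), calcium pumps, channels and sensors 6 and 5 of 19 (-0.23, mean 0.15), flavonoid and anthocyanin 7 and 6 of 14 (0.68), and the circadian clock 2 and 4 of 12 (-0.30). Camera adjusted p was 0.766 to 0.961 for the lists from the salicylic acid list on. Counts adjusted over the list alone differed for SnRK2 kinases (6 and 2), ABA synthesis and breakdown (8 and 1), salicylic acid (0 and 4) and auxin (3 and 10). Among immune genes, PR5, a defence protein gene, was at -2.83, CYP81F2 of indole glucosinolate synthesis at -1.85 and PAD4 at -0.91, while PR1, ICS1 and SNC1 were not called (adjusted p = 0.636, 0.706 and 0.385).

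In WT, mannitol against mock asked what osmotic stress changed. Mannitol raised much the same dehydration, LEA, PP2C and transcription factor genes as ABA. Immune receptors, genes of pattern-triggered immunity and clock genes had more rises than falls. Most photosystem, chlorophyll synthesis, cell wall, cell cycle, auxin and stomatal genes fell.

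Mannitol in WT led to 10977 called genes, 5545 higher and 5432 lower (1774 and 1647 at least 2-fold, median of all genes 0.02). LTP4 rose by 8.48 ± 0.45, RAB18 (AT5G66400), a dehydrin gene, by 6.12 ± 0.22, RD29B by 6.39 ± 0.62 and the LEA gene EM6 (AT2G40170) by 5.72 ± 0.19. The wall enzyme gene XTH6 (AT5G65730) fell by 5.11 ± 0.22. No list passed the test with an estimated correlation (adjusted p = 0.145 to 0.903), although markers, receptors and transcription factors passed without WT mock replicate 1, with medians of 3.10, -0.89 and 1.86. Of the marker genes 21 of 21 rose (3.10, adjusted p = 0.145), of PP2C genes 9 of 9 (2.55, adjusted p = 0.189), of ABA-related transcription factors 15 of 17 (1.92, adjusted p = 0.145) and of senescence genes 13, with 2 falls, of 16 (1.62, adjusted p = 0.205). SnRK2 kinases had 7 rises and 1 fall (8 and 1 adjusted over the list alone), ABA synthesis and breakdown 8 and 1, compatible solutes 7 and 2, DREB/CBF genes 8 and 0, and heat shock 6 and 2 (1.48). NCED3 rose by 3.54 ± 0.22 and P5CS1 by 2.35.

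NLR immune receptors rose in 8 of 18 cases in WT after mannitol (7 adjusted over the list alone, median 0.34, adjusted p = 0.534), with the helper receptor gene ADR1-L1 at 1.2, and pattern-triggered immunity had 11 rises and 1 fall of 19 (0.44, adjusted p = 0.424), with PAD3, an enzyme gene of camalexin synthesis, at 2.39. The clock had 7 rises and 0 falls of 12 (0.41), the ethylene list 7 and 3 (7 and 4 adjusted over the list alone, 0.32), wax and suberin 7 and 2 (0.15), salicylic acid 5 and 6 (-0.33), jasmonate 4 and 7 (-0.24) and calcium 4 and 3 (-0.05), which was 5 and 5 with the length trend removed. Photosystem and Rubisco genes had 23 falls of 37 (25 adjusted over the list alone, -0.58, adjusted p = 0.424), chlorophyll synthesis 11 of 12 (-0.78), auxin 12 of 18 (-0.83, adjusted p = 0.164), cytokinin response regulators 8 of 9 (-0.89), the cell cycle 12 of 18 (14 adjusted over the list alone, -0.66), receptors 7 of 10 (9 adjusted over the list alone, -0.84) and stomatal markers 5 of 8 (-1.01). Cell wall genes had 13 falls and 1 rise of 22 (14 and 1 adjusted over the list alone, -0.81), aquaporins 10 and 3 of 19 (-0.49) and flavonoid genes 9 and 2 of 14 (-0.87). Root hair and endodermis markers had 2 falls of 13, and 0 adjusted over the list alone (-0.04).

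ABA and mannitol responses in WT were compared for shared genes. Genes higher after both numbered 3147, where independent responses would share 1050, and genes lower after both numbered 4267 (1661 if independent), with 380 in opposite directions (2724 if independent). Both responses use the same 3 mock libraries, so their spread is shared. Across genes, which are not independent replicates, r was 0.762 with a covariance of 0.549, against r of 0.5 and a covariance of 0.0312 in simulated unchanged groups with the same sharing. Of the 976 genes raised at least 2-fold by both treatments in WT, 723 rose in bon123 after ABA. After mannitol in bon123, 260 of them rose and 319 fell, where 2748 of all 21727 tested genes rose and 10606 fell before any rescaling.

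The next comparison asked how bon123 responded to ABA. Most dehydration marker and PP2C genes rose in the mutant, as did most ABA-related transcription factors and wax and suberin genes. Most aquaporins, which carry water through membranes, and most photosystem, chlorophyll synthesis and NLR genes fell. Most cell cycle and cell wall genes also fell.

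In bon123 after ABA, 15341 genes were called, 3288 higher and 12053 lower (1627 and 6370 at least 2-fold). The median of all genes was -0.51, and the median-of-ratios scaling shifted it by 0.48, upper-quartile scaling by 0.26 and removal of the length trend by 0.56. The split was then 7138 higher and 7546 lower, 4992 and 9659, and 7795 and 7253, so the excess of falls depends on the scaling. RAB18 rose by 9.15 ± 0.22, RD29B by 8.65 ± 0.62, HAI3 (AT2G29380) by 8.60 ± 0.20, EM6 by 8.44 ± 0.19 and KIN1 (AT5G15960) by 7.87 ± 0.24, although KIN1 and KIN2 share reads. Large falls were those of EARLI1 at -9.08 ± 0.41, GLL23 (AT1G54010), a lipase-like gene, at -6.95 ± 0.22 and the receptor gene PYL6 (AT2G40330) at -6.04 ± 0.12. Marker genes rose in 20 of 21 cases (median 4.08 against -0.51 for all genes, adjusted p = 0.0455), a pass lost without WT mock replicate 3, WT ABA replicate 1, WT mannitol replicate 1 or 3, bon123 mannitol replicate 3 or any 1 library of bon123 mock or bon123 ABA (medians 4.01 to 4.16). PP2C genes rose in 9 of 9 cases (4.31, adjusted p = 0.0787), transcription factors in 15 of 17 (2.3, adjusted p = 0.0516), a list that passed without WT mock replicate 1 or 2 or WT ABA replicate 2 or 3 at the same median of 2.3. Heat shock had 8 rises and 1 fall of 12 (1.31, adjusted p = 0.0787), which passed without WT ABA replicate 3 at the same median of 1.31. ABA synthesis and breakdown had 7 and 2 of 11 (1.54, adjusted p = 0.0794), senescence 13 and 2 (1.74, adjusted p = 0.115), wax and suberin 10 and 3 (1.74, adjusted p = 0.248) with the suberin regulator gene MYB41 at 5.37 ± 0.26, and compatible solutes 6 and 2 (0.77).

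Aquaporin genes fell in 18 of 19 cases in bon123 after ABA (median -2.21, adjusted p = 0.319, and 1 rise and 16 falls with the median-of-ratios scaling), with PIP2;3 at -3.79 ± 0.13. Photosystem and Rubisco genes had 32 falls of 37 (-1.95, adjusted p = 0.581, 30 falls and 1 rise with the ratio scaling), with LHCB3 at -3.32 ± 0.14. Chlorophyll synthesis had 1 rise and 10 falls (-2.16, adjusted p = 0.513), cell wall 1 and 15 (-1.59), the cell cycle 1 and 15 (-1.06), NLR receptors 1 and 16 (-1.29, with 2 and 11 under the ratio scaling), salicylic acid 0 and 13 (-0.78, with 2 and 8), ABA receptors 1 and 7 (-1.70) and cytokinin response regulators 1 and 6 (-1.24). Other lists lay close to the median of all genes and turned direction. The ratio scaling gave medians of 0.05 for pattern-triggered immunity (1 rise and 11 falls, -0.44 unscaled), 0.01 for jasmonate (3 and 10, -0.56), 0.43 for ethylene (5 and 6, -0.25), 0.39 for calcium (5 and 5, -0.29), 0.51 for the clock (3 and 4, -0.09) and 0.12 for root markers (4 and 6, -0.43). Flavonoid (1 and 6, -0.46), auxin (3 and 7, -0.15) and stomatal genes (0 and 2, -0.07) turned to 0.10, 0.43 and 0.47 with the length trend removed. SnRK2 kinases had 4 rises and 3 falls (8 and 2 with the ratio scaling), and DREB/CBF genes 3 and 3 (4 and 3 adjusted over the list alone, 6 and 1 with the ratio scaling).

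**Figure D2:**
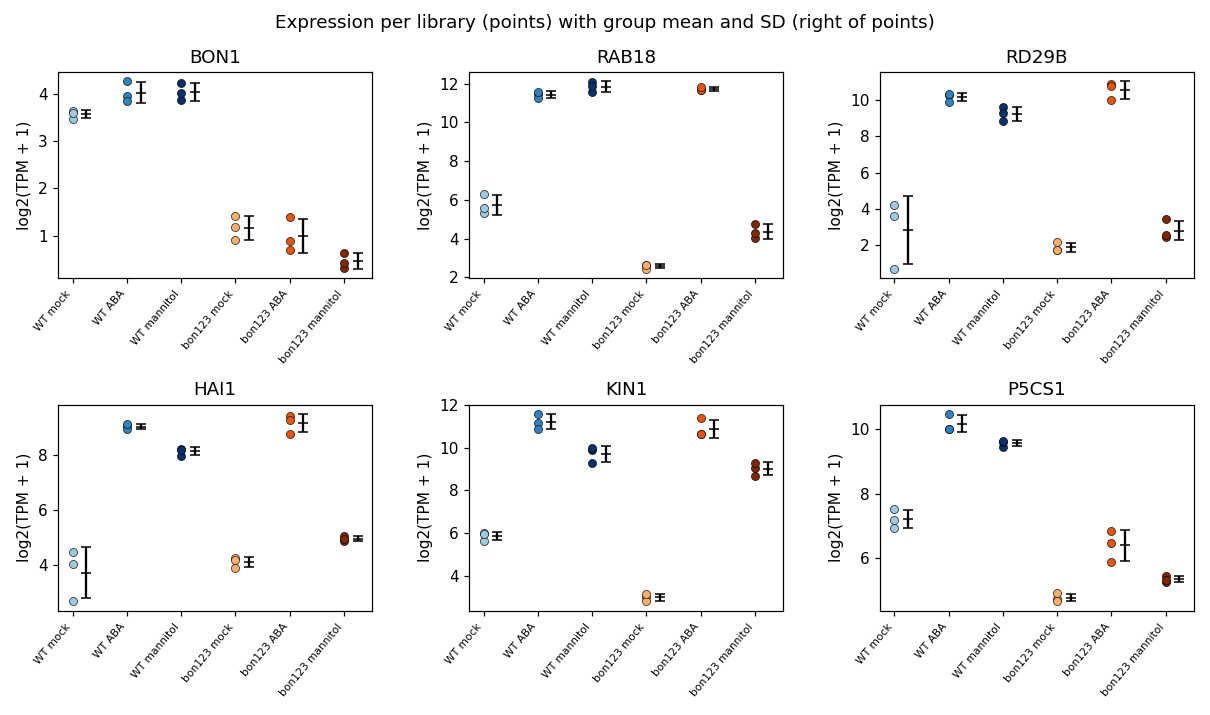
Expression of BON1, RAB18, RD29B, HAI1, KIN1 and P5CS1 as log2(TPM + 1) on the vertical axis in the 6 groups on the horizontal axis, with a point per library and the mean and SD of 3 libraries to the right of the points. HAI1 averaged 522 TPM after ABA and 280 TPM after mannitol in WT, and 580 and 30.3 TPM in bon123.

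The response of bon123 to mannitol was the next question. Most dehydration marker genes rose in the mutant, most of them by less than in WT. KIN1, a cold and dehydration gene, and RD29A rose most among the markers. Some root markers rose, and most NLR immune receptors and the clock genes PRR9 and CCA1 fell.

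In bon123 after mannitol, 13354 genes were called, 2748 higher and 10606 lower (748 and 4090 at least 2-fold). The median of all genes was -0.36 and shifted by 0.38 with the ratio scaling (6377 higher and 6050 lower), 0.36 with upper-quartile scaling (6074 and 6423) and 0.38 with the length trend removed (6268 and 6251). Fold changes fell with transcript length (Spearman's rho -0.405 across genes), with medians of 0 in the shortest of 5 length classes and -0.88 in the longest, while in the ABA and mannitol responses of WT and the ABA response of bon123 rho was within 0.081 of 0. U4.2 (AT3G06900), a small nuclear RNA of the spliceosome chosen for its size of change, rose by 6.27 ± 1.67, from 3.70 to 185 TPM, beside the ribosomal RNA shares given above. MT1A, inside another gene on the same strand, was listed at 0 in all 9 WT libraries, at 15578, 0 and 0 TPM in bon123 mock and at 28369, 28467 and 30532 TPM in bon123 mannitol, and its value is uncertain.

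KIN1 rose by 6.0 ± 0.24 in bon123 after mannitol, RD29A (AT5G52310) by 3.14 ± 0.24 and EM6 by 2.59, while RD29B was not called (0.92 ± 0.62, adjusted p = 0.207). Falls were called for DIN1 (AT4G35770), a senescence gene, at -3.07 ± 0.23 and for the clock genes PRR9 (AT2G46790) and CCA1 (AT2G46830) at -2.87 ± 0.18 and -2.13. Marker genes had 13 rises and 1 fall of 21 (median 1.1, adjusted p = 0.51, 15 and 0 with the ratio scaling). PP2C genes had 4 rises and 2 falls of 9 (4 and 3 adjusted over the list alone, 0.40), with HAI3 at 2.03 and HAB1 at -1.37. NCED3 rose by 1.95, and P5CS1 rose by 0.58 ± 0.20, no longer called without bon123 mock replicate 1 or 2 or bon123 mannitol replicate 2 (0.53 to 0.56). NLR receptors fell in 17 of 18 cases (-1.26, 16 with the ratio scaling and 10 with the length trend removed), with RPP4 at -1.96, and the clock had 4 rises and 8 falls (-1.12). Senescence had 2 and 11 (2 and 12 adjusted over the list alone, -0.89), heat shock 2 and 7 (2 and 8, -0.63), SnRK2 kinases 0 and 7 (-0.72, with 3 and 5 under the ratio scaling), salicylic acid 1 and 11 (-0.63, with 3 and 6), chlorophyll synthesis 0 and 9 (-0.82), photosystem genes 2 and 20 (-0.57, with 2 and 4 under the ratio scaling) and DREB/CBF genes 2 and 5 (3 and 5, -0.59), which turned to 4 and 3 (-0.23) under the ratio scaling. Receptors had 0 and 8 (1 and 8, -0.68), with 1 and 2 under the ratio scaling, and pattern-triggered immunity 2 and 10 (-0.53), which was 6 and 5 with the length trend removed. Root markers had 6 rises and 0 falls of 13 (3 adjusted over the list alone, 0.57), with the expansin gene EXPA18 at 2.13. Lists whose direction depended on the scaling were ABA-related transcription factors (4 and 7, -0.29, turning to 7 and 3, 0.16 with the ratio scaling), ethylene (4 and 6, -0.13, to 8 and 3, 0.38), aquaporins (6 and 5, -0.10, to 10 and 0, 0.41), cell wall (9 and 7, -0.02, to 11 and 4, 0.34), cytokinin response regulators (0 and 4, -0.33, to 2 and 2, 0.04) and stomatal markers (0 and 2, -0.04, to a median of 0.03). Jasmonate (3 and 7) became 6 and 5, ABA synthesis and breakdown (3 and 4) 4 and 3, compatible solutes (2 and 3) 6 and 1, and the cell cycle (2 and 3) 9 and 0. Auxin had 4 rises and 3 falls, flavonoid 0 and 2, wax and suberin 6 and 3, and calcium 0 and 10 (-0.42), which became 2 and 6 under both the ratio and the upper-quartile scaling, with medians of -0.05 and 0.04. Camera adjusted p was 0.51 to 0.859 over the 28 lists.

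**Figure D3:**
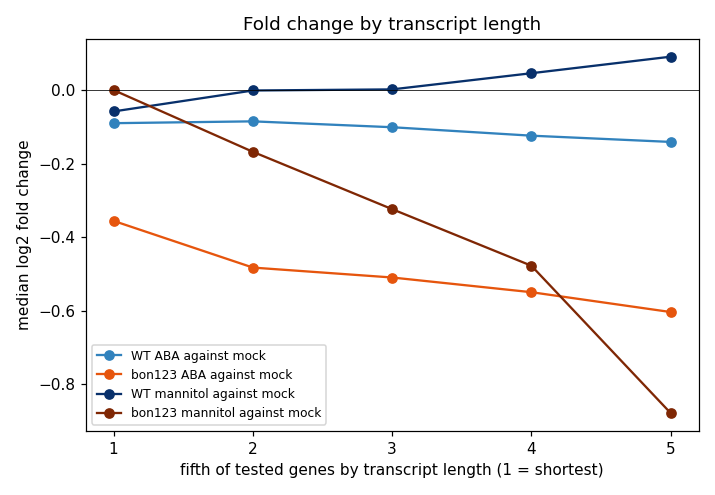
Median log2 fold change (vertical axis) of the tested genes in 5 classes of transcript length with equal gene numbers (horizontal axis, 1 is the shortest), with a line for each treatment response in each genotype. The bon123 mannitol line falls from 0 in the shortest class to -0.88 in the longest.

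**Figure D4:**
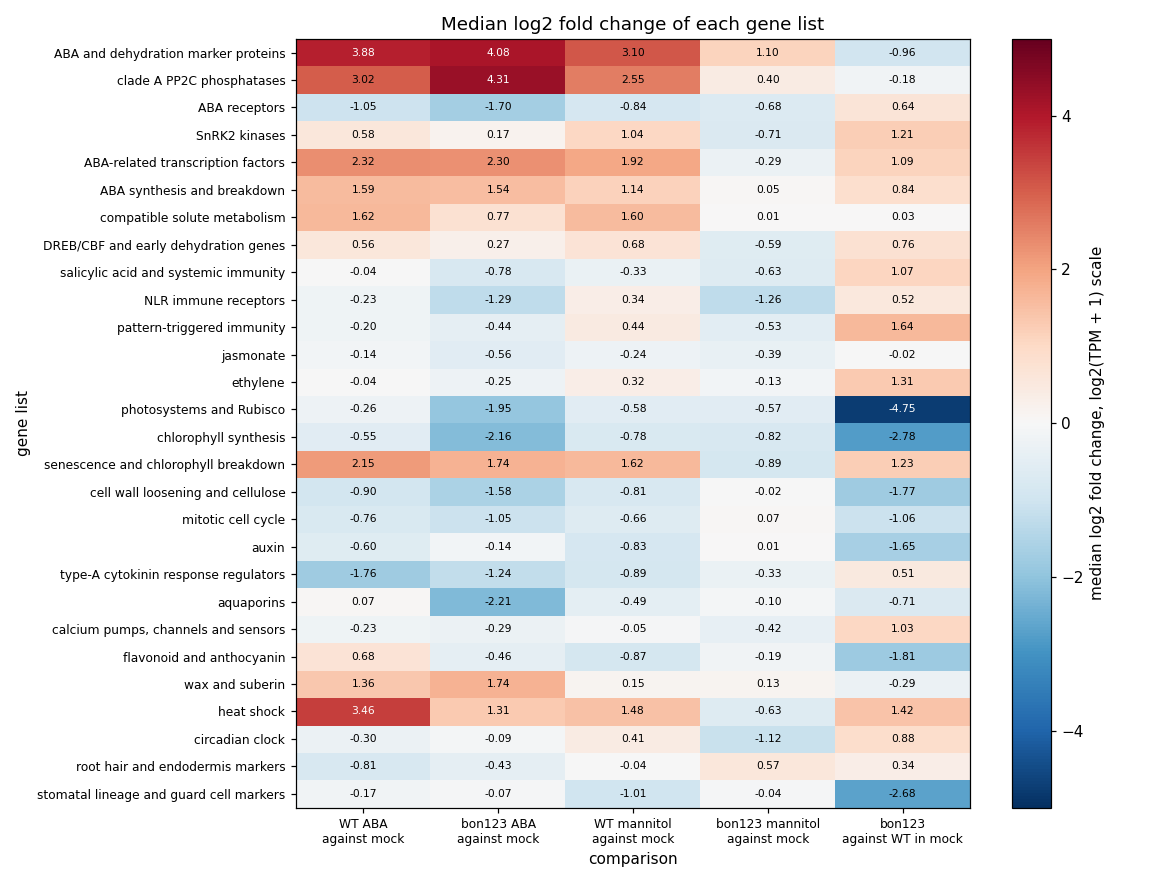
Median log2 fold change (colour and printed value) of each gene list (vertical axis) in 5 comparisons (horizontal axis). Marker genes had medians of 3.88 and 3.10 in WT and 4.08 and 1.1 in bon123 after ABA and mannitol, and near-0 medians in the bon123 columns turned sign under other scalings for the lists named with each comparison.

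Without stress, bon123 was compared with WT to ask what the mutations changed. Genes of photosystems and Rubisco, the enzyme that fixes carbon dioxide, were far lower in the mutant, as were most genes of chlorophyll synthesis, flavonoids, cell wall loosening, auxin, stomata and the cell cycle. Most genes of pattern-triggered immunity, ethylene and salicylic acid signalling were higher, among them the defence marker PR1. Calcium, senescence and clock genes were mostly higher. Dehydration markers were split.

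Mock-treated bon123 and WT differed in 16036 genes, 8722 higher and 7314 lower in bon123 (4499 and 4285 at least 2-fold). The median of all genes was 0.13, and the ratio scaling shifted it by -0.16 (7637 higher and 8257 lower) and upper-quartile scaling by -0.19 (7372 and 8591). RBCS2B (AT5G38420), for the small Rubisco subunit, was at -10.08 ± 0.75, a copy that shares reads with its relatives, and CA1 (AT3G01500), for a carbonic anhydrase, at -9.21 ± 0.56. PR1 (AT2G14610) was at 7.95 ± 0.88, or 14.1 TPM in WT and 2527 TPM in bon123, and PSK2 (AT2G22860), for a peptide hormone, at 8.09 ± 0.17. No list passed (adjusted p = 0.292 to 0.949). Photosystem and Rubisco genes were lower in 37 of 37 cases (median -4.75, adjusted p = 0.292), chlorophyll synthesis in 12 of 12 (-2.78, adjusted p = 0.292) with PORC at -5.45 ± 0.11, the cell cycle in 18 of 18 (-1.06, adjusted p = 0.402), flavonoid genes in 13 of 14 (-1.81, adjusted p = 0.402) and stomatal markers in 7 of 8 (-2.68, adjusted p = 0.292), with TMM, a receptor of stomatal patterning, at -3.14. Root hair and endodermis markers had 4 higher and 0 lower of 13 (2 adjusted over the list alone, 0.34), which was 2 and 2 with upper-quartile scaling. Auxin had 3 higher and 14 lower (-1.65, adjusted p = 0.292), cell wall 3 and 17 (-1.77, adjusted p = 0.352), aquaporins 3 and 10 (-0.71) and wax and suberin 5 and 7 (-0.29), with CER6, a wax elongase gene, at -5.23.

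Pattern-triggered immunity genes were higher in unstressed bon123 in 16 of 19 cases and lower in 1 (median 1.64, adjusted p = 0.402), with the kinase gene BIK1 at 3.20. Ethylene had 16 and 1 (1.31, adjusted p = 0.402), salicylic acid 15 and 3 (1.07, adjusted p = 0.538) with the regulator gene SARD1 at 3.53 and PAD4 (AT3G52430) at 1.48 ± 0.17, and NLR receptors 10 and 2 (0.52, adjusted p = 0.735). The salicylic acid synthesis gene ICS1 (0.08, adjusted p = 0.639) and the NLR gene SNC1 (-0.00, adjusted p = 0.997) were not called. Calcium had 13 and 2 (1.03) with BAP1, which encodes a BON1 partner, at 4.70. Higher and lower members were 12 and 1 in senescence (1.23), 8 and 1 in heat shock (1.42), 9 and 1 in the clock (0.88), 8 and 2 among SnRK2 kinases (1.21), 13 and 3 among transcription factors (1.1), 7 and 1 among receptors (0.64), 6 and 2 among DREB/CBF genes (0.76), 6 and 3 in ABA synthesis and breakdown (0.84), 6 and 2 among cytokinin response regulators (0.51), 9 and 9 in jasmonate (-0.02), 1 and 2 among PP2C genes (-0.18) and 4 and 4 among compatible solutes (0.03, turning to -0.17 with the ratio scaling). Marker genes had 6 higher and 10 lower of 21 (-0.96, adjusted p = 0.735). RD22 (AT5G25610) was at -7.17, COR15A (AT2G42540) at -5.10 and RD29A at -4.72 ± 0.24, and P5CS1 at -2.44.

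Under ABA, bon123 against WT asked which genes differed between hormone-treated plants. Most photosystem, chlorophyll synthesis and aquaporin genes were lower in the mutant. PP2C genes were mostly higher. The defence gene PR1 was again higher.

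In ABA 16601 genes differed, 6283 higher and 10318 lower (3580 and 6772 at least 2-fold, median of all genes -0.31, shifted by 0.31 with the ratio scaling to 8585 higher and 8678 lower, and by 0.38 with the length trend removed to 9139 and 8369). Photosystem and Rubisco genes were lower in 36 of 37 cases (median -6.44), chlorophyll synthesis in 12 of 12 (-4.68), aquaporins in 18 of 19 (-2.63) and stomatal markers in 8 of 8 (-2.02). PIP2;6 (AT2G39010), an aquaporin gene, was at -7.42 ± 0.16. PP2C genes were higher in 7 of 9 cases and lower in 0 (0.80). Marker genes had 8 higher and 7 lower, with a median of 0.30 and a mean of -0.73. Pattern-triggered immunity had 14 and 3 (0.87), and PR1 was at 8.48. ADPG1 (AT3G57510), for a wall-degrading polygalacturonase, was at 8.29 ± 0.15 and LTP4 at -6.05. Camera adjusted p was 0.439 to 0.963 over the 28 lists.

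With mannitol, bon123 against WT asked the same of osmotically stressed plants. Most dehydration markers and PP2C phosphatase genes were lower in the mutant, and so were photosystem genes. Receptors of ABA, salicylic acid genes and root markers were mostly higher.

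In mannitol 16216 genes differed, 5513 higher and 10703 lower (2719 and 5957 at least 2-fold, median of all genes -0.36, shifted by 0.33 with the ratio scaling to 7959 higher and 8292 lower, by 0.26 with upper-quartile scaling to 7509 and 8846, and by 0.39 with the length trend removed to 8294 and 7758). Differences fell with transcript length (rho -0.29 across genes). Marker genes had 20 lower and 1 higher of 21 (median -2.92, adjusted p = 0.632, and 13 and 1 with the ratio or upper-quartile scaling) and PP2C genes 9 lower of 9 (-2.88, adjusted p = 0.665), whereas ABA receptors had 8 higher and 1 lower (0.85). LTP4 was at -9.86 ± 0.45 and RD29B at -6.43 ± 0.62. RD22, another dehydration gene, was at -10.09 ± 0.35. Photosystem genes were lower in 37 of 37 cases (-4.51), and NLR receptors in 13, with 1 higher, of 18 (-1.27), which became 7 higher and 9 lower with the length trend removed. Salicylic acid genes had 14 higher and 5 lower (1.17), and root markers 7 and 0 of 13 (1.13). PR1 was at 8.44 and NCED3 at -2.05. Camera adjusted p was 0.615 to 0.987 over the 28 lists.

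**Figure D5:**
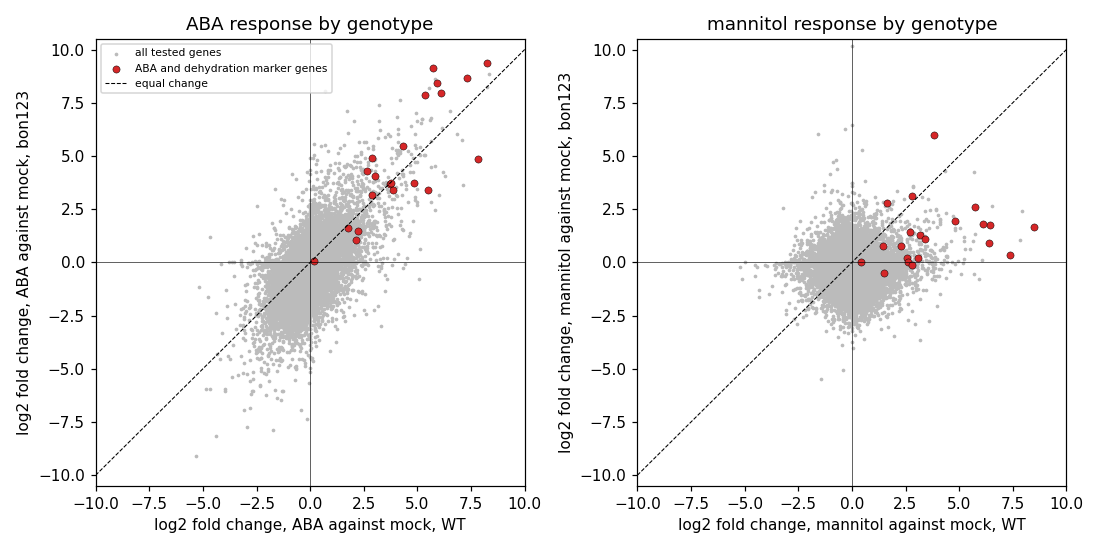
Log2 fold change after treatment in bon123 (vertical axis) against that in WT (horizontal axis), with a point per tested gene, marker genes in red and a dashed line at equal change, for ABA on the left and mannitol on the right. Marker genes had medians of 3.88 in WT and 4.08 in bon123 after ABA, and of 3.10 and 1.1 after mannitol.

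Whether the genotypes responded differently to ABA was tested by the interaction. Several dehydration and PP2C genes rose more in bon123 than in WT. Most aquaporin and photosystem genes and many flavonoid genes had negative interactions. For RD29A, KIN1 and RAB18 the larger change started from a lower mock level, and RD29A did not reach the WT level. The proline synthesis gene P5CS1 rose less.

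The ABA interaction held 11420 called genes, 2067 positive and 9353 negative (1125 and 4582 at least 2-fold), around a median of -0.44 for all genes that the ratio scaling shifted by 0.48, to 5122 positive and 4674 negative genes, upper-quartile scaling by 0.29 (3438 and 6379) and removal of the length trend by 0.47 (5524 and 5329). RAB18 was at 3.44 ± 0.31 and KIN1 at 2.52 ± 0.34. RAB18 averaged 54.1 TPM in mock and 2781 in ABA in WT and 4.98 and 3403 TPM in bon123. RD29A was at 2.05 ± 0.34. RD29A averaged 58.6 TPM in mock and 426 in ABA in WT and 1.2 and 68.4 TPM in bon123. KIN1 averaged 57.4 and 2401 TPM in WT and 7.03 and 1922 TPM in bon123, with overlapping libraries in ABA. P5CS1 was at -1.33 ± 0.28. Marker genes had 8 positive and 4 negative interactions of 21 (median 0.30, adjusted p = 0.694, 9 and 1 with the ratio scaling), and PP2C genes 5 and 0 of 9 (1.05, adjusted p = 0.694), with HAI3 at 2.8 ± 0.28. Aquaporins had 17 negative of 19 (-2.31, adjusted p = 0.694, 16 with the ratio scaling), photosystem genes 30 of 37 (-1.71, 24 with the ratio scaling) and flavonoid genes 9, with 1 positive, of 14 (-1.71). Of the 1521 genes that ABA raised at least 2-fold in WT, 1077 rose in bon123, 151 fell and 293 were not called. Their medians were 1.61 in WT and 1.13 in bon123, and the choice of genes on WT favours the WT median. Over all 21727 tested genes 3288 rose and 12053 fell in bon123 before any rescaling. Across genes the ABA responses of both genotypes correlated with r of 0.632.

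The mannitol interaction asked the same for osmotic stress. Most dehydration markers, PP2C phosphatases, SnRK2 kinases, ABA-related transcription factors, senescence genes and heat shock genes had negative interactions. Most cell cycle and auxin genes and some cell wall genes had positive interactions. KIN1 had a positive interaction, from a lower mock level in bon123.

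For mannitol 13538 genes had an interaction, 3685 positive and 9853 negative (1995 and 5936 at least 2-fold), around a median of -0.42 for all genes. The ratio scaling shifted that by 0.48 (6688 positive and 6069 negative), upper-quartile scaling by 0.46 (6595 and 6309) and removal of the length trend by 0.42 (6448 and 6696). Interactions fell with transcript length (rho -0.327 across genes, with medians of 0.08 in the shortest length class and -1.0 in the longest), and ribosomal RNA was 5.90% to 10.1% in the bon123 mannitol libraries. LEA7 was at -7.05 ± 0.84, LTP4 at -6.80 ± 0.64 and RD29B at -5.47 ± 0.87, whereas RD29A had no called interaction (0.33 ± 0.34, adjusted p = 0.405). NCED3 was at -1.59 ± 0.31 and P5CS1 at -1.77 ± 0.28. RAB18 at -4.33 and KIN1 at 2.16 fall outside the naming rule and were chosen after their values were seen. KIN1 went from 57.4 to 854 TPM in WT and from 7.03 to 519.8 TPM in bon123. Marker genes had 17 negative and 2 positive interactions of 21 (median -2.36, adjusted p = 0.429, and 16 and 3 with a median of -1.76 under the ratio scaling). PP2C genes had 9 negative of 9 (-2.15, adjusted p = 0.383), SnRK2 kinases 9 of 10 (-1.48, adjusted p = 0.317), transcription factors 15 of 17 (-2.05, adjusted p = 0.317), senescence 15 of 16 (16 adjusted over the list alone, -2.42, adjusted p = 0.317), heat shock 10 of 12 (-1.91, adjusted p = 0.317) and NLR receptors 17 of 18 (-1.85, adjusted p = 0.417, 13 with the length trend removed). The cell cycle had 12 positive of 18 (0.69, adjusted p = 0.317), auxin 11 positive and 1 negative (0.84, adjusted p = 0.274) and cell wall 10 and 3 of 22 (0.75, adjusted p = 0.317), with XTH4 (AT2G06850) at 3.33 ± 0.23. XTH6 was at 4.32 ± 0.31, but at 1.23 TPM in bon123 mock against 139 TPM in WT mock it had little room to fall. Salicylic acid genes had 2 positive and 8 negative interactions (-0.36), which turned to 5 and 4 with a median of 0.20 under the ratio scaling. Of the 1774 genes that mannitol raised at least 2-fold in WT, 408 rose in bon123, 652 fell and 714 were not called, and of the 1647 that it lowered, 567 fell in bon123, 263 rose and 817 were not called. Over all 21727 tested genes 2748 rose and 10606 fell in bon123, a split that the ratio scaling evens. Genes called higher in both genotypes at any fold numbered 897, where independent responses would share 701. Those lower in both numbered 2432 (2652 if independent), and 3471 changed in opposite directions (3394 if independent). The medians of the raised genes were 1.45 in WT and -0.16 in bon123, and the choice of genes on WT favours the WT median. Across genes the mannitol responses of both genotypes correlated with r of 0.035. Length was not corrected for in this r or in the counts shared by both genotypes. Fold changes after mannitol had a rho with transcript length of -0.405 in bon123 and 0.077 in WT.

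Among gene ontology terms, genes raised at least 2-fold by ABA in WT held 74 of 210 genes of the response to water deprivation (14.9 expected, adjusted p = 3.49e-29, one-sided Fisher's exact test) and those raised by mannitol 72 (17.7 expected, adjusted p = 5.69e-23). Photosynthesis held 115 of its 144 genes among those lower in unstressed bon123 (29.8 expected, adjusted p = 9.71e-49), and defence to fungus 87 of 182 among those higher (38.1 expected, adjusted p = 3.39e-13). With the length trend removed, genes of negative mannitol interaction held 63 of 210 water deprivation genes (26.3 expected, adjusted p = 3.79e-09), and those of positive interaction 30 of 41 cytoplasmic translation genes (6.5 expected, adjusted p = 4.03e-13). Genes within a term are not independent of each other.

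Response scores summarised each treatment over the genes that changed in the average of both genotypes, which need not have changed in each. The ABA score, from 1397 rising and 3661 falling genes, changed by 2.76 in WT and 4.2 in bon123, a difference of 1.44 (two-sided exact permutation p = 0.18). Differences between single treated and mock libraries were 2.54 to 3.02 in WT and 4.14 to 4.29 in bon123. Because the arrangements mix the difference between genotypes into the score, this p-value does not show equal responses. Nor do the ranges alone show a stronger response in bon123, as score genes were chosen from these same libraries. Falls of at least 2-fold after ABA numbered 1676 in WT and 6370 in bon123, so bon123 weighs more in the choice of falling genes. Rising genes gained 1.81 in WT and 2.17 in bon123, and falling genes changed by -0.95 and -2.03. The mannitol score, from 636 and 1058 genes, changed by 3.36 in WT and 2.45 in bon123, a difference of -0.92 (exact permutation p = 0.015). Mean mannitol scores were 1.84 in WT and 1.79 in bon123 after mannitol, and -1.525 and -0.66 in mock. The genotypes thus differed in this score mainly in mock. For mannitol, rising genes gained 2.21 in WT and 1.02 in bon123, and falling genes changed by -1.16 and -1.43. Without 1 library the mannitol p passed 0.05 or reached it in 6 cases: WT mock replicate 2 (-1.08, p = 0.05), WT mock replicate 3 (-1.01, p = 0.07), WT mannitol replicate 3 (-0.89, p = 0.1), bon123 mock replicate 2 (-0.96, p = 0.06), bon123 mock replicate 3 (-0.93, p = 0.065) and bon123 mannitol replicate 1 (-0.75, p = 0.095), each by exact permutation. The call was also lost with score genes of any fold (-0.19, exact permutation p = 0.58) and with the ratio scaling (-1.02, exact permutation p = 0.12). The difference of genotypes in mock and the WT responses correlated across genes with r of 0.272 for ABA and 0.39 for mannitol, both comparisons sharing the WT mock libraries, where simulated unchanged groups gave 0.505 and 0.5. The covariances were 0.365 and 0.513, against 0.0314 and 0.0311 simulated. With no library shared, the difference of genotypes in ABA correlated with the WT mannitol response at r of 0.288. The difference of genotypes in mannitol correlated with the WT ABA response at r of -0.131, so the direction was not the same in each treatment.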

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

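What the transcript length test would show was written down before its result was seen, whereas the tests of scaling, ribosomal RNA, green shoot share and overlapping genes, and the readings of the other splits, were chosen or written after the results were seen. Results are given here because the response of one genotype differed from that of the other by a test of the difference itself. KIN1 and RAB18 in the mannitol interaction were chosen after their values were seen. KIN1 and KIN2 share reads, so single values are uncertain.

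Responses to ABA differed between genotypes in 11420 genes by the interaction term. Interactions were positive for some dehydration genes, with RAB18 at 3.44, EM6 at 2.55, KIN1 at 2.52 and RD29A at 2.05, and negative for the lipid transfer gene LTP4 at -2.99 and the proline synthesis gene P5CS1 at -1.33. RAB18, KIN1 and RD29A started from lower mock levels in bon123, as given with the ABA interaction. The phosphatase gene HAI3 was at 2.8 and the suberin genes MYB41 and GPAT5 were at 3.98 and 2.7. The sugar transporter gene SWEET13 was at 5.41, the peroxiredoxin gene PER1 at 5.37, the sulphur deficiency gene ATSDI1 at 5.10 and the transporter gene SULTR3;1 at 4.39. Most aquaporin genes were negative, with PIP2;6 at -3.59, PIP2;3 at -3.50 and PIP2;1 at -3.09, as were the light-harvesting gene LHCB3 at -3.07 and RBCS1A, a Rubisco gene that shares reads with its relatives, at -2.47. The most negative were the lipase-like gene GLL23 at -6.54, HIPP24, for a metal-binding protein, at -6.27, the cytokinin hydroxylase gene CYP735A2 at -5.09, the gibberellin synthesis gene GA3OX1 at -4.92 and the ammonium transporter gene AMT1;2 at -4.82. CYP735A2 had little room to fall in WT, at 1.73 TPM in mock and 0.05 in ABA, against 112 and 0.28 in bon123. Smaller negative interactions were BON1 at -0.63, ICS1 at -0.71 and SNC1 at -0.75. BON1 was low in bon123, at 1.27 TPM in mock and 1.03 in ABA, against 10.9 and 15.4 in WT. The BON1 call was lost without any 1 of 9 of the 12 libraries compared, the exceptions being WT ABA replicate 3, bon123 mock replicate 1 and bon123 ABA replicate 3, and the SNC1 call without any of 9, the exceptions being WT ABA replicate 2 and bon123 ABA replicates 1 and 2. For BON1 in interaction of genotype and ABA the lowest and highest values at a lost call were -0.66 and -0.48, and for SNC1 in interaction of genotype and ABA they were -0.81 and -0.41.

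Responses to mannitol differed in 13538 genes, and the mannitol score differed by -0.92 (two-sided exact permutation p = 0.015), a result that 6 of 12 omissions of a library ended, as given with the score, as did score genes of any fold (-0.19, exact permutation p = 0.58) and the ratio scaling (-1.02, exact permutation p = 0.12). Mean mannitol scores of the genotypes were close after mannitol and apart in mock, as given with the score. Many dehydration genes had strongly negative interactions, LEA7 at -7.05, LTP4 at -6.80, RD29B at -5.47, LTP3 at -4.71 and RAB18 at -4.33, but KIN1 was at 2.16. The phosphatase genes HAI1, HAB1 and HAI2 were at -3.56, -3.29 and -3.01, the transcription factor genes HB12 and NAC019 at -3.49 and -3.04, and the kinase gene SNRK2.7 at -3.06. The senescence genes SAG13 and PAO were at -4.21 and -4.09, the chaperone genes HSP17.4 and HSP17.6A at -5.61 and -4.91, and the clock genes PRR9 and PRR7 at -2.90 and -2.86. NCED3 of ABA synthesis was at -1.59, P5CS1 at -1.77, and the NLR genes RPP4 and SNC1 at -2.49 and -1.95. Fewer NLR genes had negative interactions with the length trend removed, as given with the mannitol interaction. BON1 and BON2 were at -1.17 and -1.48. BON1 was low in bon123, at 1.27 TPM in mock and 0.39 in mannitol, against 10.9 and 15.5 in WT. Some cell wall genes were positive, XTH6 at 4.32 (at 1.23 TPM in bon123 mock, with little room to fall), EXPA8 at 4.23, EXPB3 at 3.83 and XTH4 at 3.33, as were the cyclin gene CYCD3;2 at 1.73, the auxin response gene IAA3 at 2.98 and the aquaporin gene TIP2;1 at 2.31. IAA3 and EXPA8 also had little room to fall, at 1.56 and 2.4 TPM in bon123 mock against 55.9 and 45.3 in WT mock. Both rose in bon123 after mannitol, by 0.98 and 1.64.

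Other splits of the libraries were run for each count of genes. For comparisons of 2 groups, 10 splits are too few for a share under 0.05, the real split being the 1 as large in each. The real value and the highest of the other splits were 10759 and 6 for WT ABA, 10977 and 73 for WT mannitol, 15341 and 9 for bon123 ABA, 13354 and 2 for bon123 mannitol, 16036 and 0 for bon123 against WT in mock, 16601 and 1 in ABA, and 16216 and 1 in mannitol. For the interactions, 100 of 200 splits of genotypes within treatments were drawn. With ABA 7 of 100, the real split included, gave at least the real 11420 genes (highest other 13059), so chance cannot be excluded by this test, and a second draw gave 4 of 100 (highest other 17778). The others as large in the first draw kept the treated libraries in their genotypes and moved mock libraries between them, which brings the large difference between genotypes into the interaction. With mannitol 1 of 100 was as large (real 13538, highest other 10752). Splits that mix the genotypes within a group also put their difference into the spread, which lowers the counts, so this test does not settle whether chance can be excluded.

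The weaker mannitol response of dehydration marker genes in bon123 was a median interaction of -2.36. Medians are over genes. Each SE given here, and below for the photosystem and root marker genes, is that of the same comparison made on per-library medians. Scaling between libraries as the whole cause is argued against by a median of -1.76 (SE 0.317) after the median-of-ratios scaling. Ribosomal RNA as the whole cause is argued against by -2.24 (SE 0.334) without its genes, and transcript length by -2.42 (SE 0.30) relative to the 200 tested genes nearest in length to each marker. Lower RNA quality of the bon123 mannitol libraries in other respects, and a difference between genotypes in the signalling of osmotic stress, may both contribute and stay open, as neither was tested. Part of any excess of shared changes may come from the 3 mock libraries in common, which cannot be split with 2 in each part. For the WT responses, a covariance of 0.549 against 0.0312 in simulated unchanged groups argues against the spread of these libraries as the whole cause.

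Photosystem and Rubisco genes were lower in unstressed bon123 with a median of -4.75. Scaling between libraries is argued against by -4.94 (SE 0.139) after the median-of-ratios scaling. A smaller share of green shoot tissue in bon123 seedlings would raise root markers. These had a median of 0.34, little above its SE of 0.277. The markers do not settle the size of any change of share, so a change of tissue share and a change within green cells cannot be told apart. A developmental or immune effect of the mutations may also lie behind the difference and was not tested.

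LHCB1.5, a light-harvesting gene, varied widely between libraries of WT groups, being listed at 11253, 15.6 and 10968 TPM in the 3 WT ABA libraries. Its overlapping neighbour AT2G08665 was at 0, 11485 and 2917 TPM in the same libraries. Reads assigned to one or the other gene are a candidate explanation, since the coefficient of variation of their sum was 0.139 of that of LHCB1.5 (median over the 3 WT groups). The fold change of LHCB1.5 alone is therefore uncertain.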

How the results depend on the processing

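Pseudocounts, the 5 TPM minimum, both scalings, omission of ribosomal RNA and removal of the length trend were chosen after seeing the data, and the other alternatives were planned. DESeq2, edgeR factors, filterByExpr and scaled-CPM scores were not run because the values are TPM. Of 1155 results for named genes, 975 kept their direction and side of the threshold under each alternative run, and 8 reversed in at least 1. With no filter, the 5 TPM minimum, pseudocounts of 0.1 and 5, an adjusted p under 0.01, only the groups compared, or any 1 library left out, each contrast count stayed within 1.5 times. Unknown read depth limits what can be said of weakly expressed genes.

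Asking for at least 2-fold changes lowered each count by construction. WT ABA then had 3197 genes (1521 higher, 1676 lower), WT mannitol 3421 (1774, 1647), bon123 ABA 7997 (1627, 6370), bon123 mannitol 4838 (748, 4090), bon123 against WT 8784 in mock (4499, 4285), 10352 in ABA (3580, 6772) and 8676 in mannitol (2719, 5957), the ABA interaction 5707 (1125, 4582) and the mannitol interaction 7931 (1995, 5936). The overlap of WT responses went from 7414 to 1777.

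For other changes of counts the cause was not tested. The median-of-ratios scaling gave 7138 higher and 7546 lower genes for bon123 ABA, 6377 and 6050 for bon123 mannitol, 5122 and 4674 for the ABA interaction and 6688 and 6069 for the mannitol interaction. Upper-quartile scaling gave 4992 higher for bon123 ABA, 6074 and 6423 for bon123 mannitol, 3438 higher for the ABA interaction and 6595 and 6309 for the mannitol interaction. Removal of the length trend gave 7795 and 7253 for bon123 ABA, 6268 and 6251 for bon123 mannitol, 8294 higher in bon123 against WT in mannitol, 5524 and 5329 for the ABA interaction and 6448 higher for the mannitol interaction.

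Gene list tests passed in 4 cases, and in 126 with the preset correlation, 188 with fry, which tests lists without comparison to other genes, 8 with the median-of-ratios scaling, 7 with upper quartiles and 2 with the length trend removed. Leaving out 1 library gave 0 to 8, with 8 without WT mock replicate 1. With the replicate number as a block 0 lists passed, while the overlap of WT responses was 7311. Replicates that share a number showed little pairing, with 7 of 45 pairs of groups correlated above 0.1 (-0.244 to 0.263). The cause was not tested for these differences.

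The ABA score difference of 1.44 stayed without a call (1.33 to 1.49 leaving out 1 library, 1.59 with the ratio scaling, 0.798 with genes of any fold). The mannitol score difference of -0.92 lost its call with genes of any fold (-0.19, p = 0.58) and the ratio scaling (-1.02, p = 0.12), ranged from -1.08 to -0.75 leaving out 1 library (two-sided exact permutation p = 0.005 to 0.1), and the cause was not tested. With only called genes, the genotype effect in mock correlated with the WT ABA response at 0.311.

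CYP707A2 in the ABA interaction became -0.38 with a pseudocount of 5. ARR9 in bon123 after mannitol became 0.25, 0.21 and 0.084 with the ratio scaling, upper quartiles and the length trend removed, and SNRK2.10 in the ABA interaction 0.077 with the ratio scaling. With the length trend removed AAO3, P5CDH and SUS3 in bon123 after mannitol became 0.11, 0.02 and 0.24, AUR2 in bon123 against WT in mannitol 0.048 and GUN5 in the mannitol interaction 0.58. The cause was not tested.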

Other observations

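The tests in this part were chosen after the data were seen. MT1A, a metallothionein gene that lies inside another gene on the same strand, was listed at 0 TPM in bon123 ABA replicates 1 and 2 and at 42791 TPM in replicate 3. Its values are uncertain.

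With the length trend removed, bon123 after ABA still had 56 of 113 genes of rRNA processing among those at least 2-fold lower (17.3 expected, adjusted p = 1.22e-14, one-sided Fisher's exact test), and 86 before (34.8 expected). Terms of signal transduction (92 of 231) and DNA repair (79 of 206) among genes lower in bon123 after mannitol no longer passed once the trend was removed.

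Across genes, the mock difference between genotypes correlated with the difference in ABA at r of 0.842 and in mannitol at 0.728, while both interactions correlated at 0.253, where simulated unchanged groups sharing the mock libraries gave 0.498. The covariance of the interactions was 0.269, against 0.0618 simulated. Genes are not independent replicates.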
